A study of Rattus norvegicus with 6 samples.

How the data were processed

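Small RNA libraries were described for 6 rat lung samples, 3 from rats given saline (control) and 3 from rats given monocrotaline (MCT), a plant alkaloid used to induce pulmonary arterial hypertension. Per the labels' protocols, total RNA was treated to remove chemical modifications that block library preparation, adapters were ligated to both RNA ends, and amplified fragments were cut from a gel by size. The same protocol text also speaks of a small RNA microarray, and the sample labels give lung where the design text of the series gives right ventricle. The submitters' processing notes name Bowtie and the mouse build mm10, with no version or role, for samples labelled as rat. The counting tool, the filter by which fragments entered the table and any pooling are not given in the sources used here.

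The deposited table lists tRNA-derived fragments (tsRNAs), short RNAs cut from tRNAs or from their precursors. Per the file headers, its columns hold an identifier, the sequence, a class, the length, the reference sequences the fragment was aligned to, and 6 columns of values in CPM, counts scaled to the size of each library. Those 6 columns are numbered under the single letter N, while the samples are titled control 1 to 3 and MCT 1 to 3. No column name matches the labels of 1 sample alone, and 6 columns share a letter while each group has 3 samples. Neither sample nor group could therefore be read from the names, and column order or content was not used in their place. The 6 columns of per-sample values were not used. The comparison of MCT with control, the tests planned for it and the depth of each library are for this reason not analysed here, and 192 further lines of the table are also not analysed here. Lists of miRNAs fixed before the data were examined could not be tested, since the listed sequences were all aligned to tRNAs or their precursors.

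The analysis was made on the 2405 listed fragments and their deposited annotation. Each fragment was placed on the first reference sequence named for it, with positions counted from 1 at the 5′ end of that reference. References fell into nuclear mature tRNAs, mitochondrial mature tRNAs, nuclear precursors and mitochondrial precursors by their names in the table. All 186 mature references ended in CCA, the triplet added to tRNAs after transcription. In 121 of the 128 precursors whose mature tRNA was also in the table, the body of the tRNA lay between flanks of 40 bases, and 6 of the others had a longer body between the same flanks. A flank of 40 bases was therefore taken as the leader on the 5′ side and as the trailer on the 3′ side. The mitochondrial Phe precursor was taken to have no leader. The listed lengths equalled the sequence length for all 2405 fragments, and 2399 fragments matched each of their references exactly at the stated position. No genome of the authors' build was used, so no chromosome coordinates are given.

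Counts of fragments are counts of distinct listed sequences and say nothing of how abundant each one was. They carry no replicate error, and sequences that overlap or differ by 1 base in length are not independent observations. The classes and amino acid families had been fixed before the data were examined, with mitochondrial tRNAs as a family of their own. The family counts below instead join the nuclear and mitochondrial tRNAs of an amino acid, a grouping that had not been fixed. The rule for naming single fragments needed per-sample values, so the longest and the shortest fragment of a class, with ties taken in order of identifier, were named instead, a rule chosen after the table was seen. In the closing section, 3′ ends of fragments with a fixed start were compared with 10000 random sets of lengths between 14 and 40 nt on the same references, one-sided, with Benjamini-Hochberg adjustment over the 4 such tests that were run. The permutation test was tested on simulated data for cuts between a pyrimidine and A on the 185 nuclear fragments from base 1. It gave p under 0.05 in 7 of 100 sets with random ends and in 100 of 100 sets in which such cuts were drawn with a weight of 4. The sets with random ends followed the test's own assumption that every length is equally probable, and weaker weights were not simulated. Shares were recomputed with 1 entry per reference and 5′ start, with 1 entry per reference and 3′ end, with fragments of at least 18 nt, with fragments of 1 reference, and without mismatched fragments. The 95% Wilson interval of each share served only as a yardstick for these alternatives. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.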

Results

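The series set out to compare tRNA-derived fragments between 3 saline-treated rats and 3 rats with pulmonary hypertension induced by monocrotaline. The samples were labelled as lung. The columns of per-sample values could not be tied to either group, so no fragment can be reported here as higher or lower after monocrotaline. The table of 2405 fragments does describe which tRNAs the detected fragments came from, where on each tRNA they lay, and how long they were. All 2405 sequences were distinct. They were 14 to 40 nt long with a median of 22 nt. They had been aligned to 315 reference sequences, made up of 165 nuclear mature tRNAs, 110 nuclear precursors, 21 mitochondrial mature tRNAs and 19 mitochondrial precursors.

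The first question the table addresses is which compartment the fragments came from. Nuclear mature tRNAs gave 955 fragments (39.7%) and mitochondrial mature tRNAs gave 899 (37.4%). Nuclear precursors gave 283 (11.8%) and mitochondrial precursors gave 268 (11.1%). With 1 entry per reference and 3′ end the nuclear precursor share was 20.4%, or 226 of 1109. Fragments of mitochondrial origin thus numbered 1167, or 48.5% of the list. Median lengths were close, at 21 nt for nuclear mature, 23 nt for mitochondrial mature, 20 nt for nuclear precursor and 23 nt for mitochondrial precursor fragments. Many nuclear fragments matched several mature sequences: 551 of the 955 nuclear mature fragments (57.7%) matched more than 1 reference, against none of the 899 mitochondrial mature ones. Across the table, 629 fragments (26.2%) matched several references, up to 10 for 1 fragment, and 239 (9.94%) matched tRNAs of more than 1 anticodon. The parent tRNA of such a fragment is uncertain. A mature reference can also stand for several gene copies, so the parent gene can be uncertain for fragments of 1 reference as well.

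**Figure D1:**
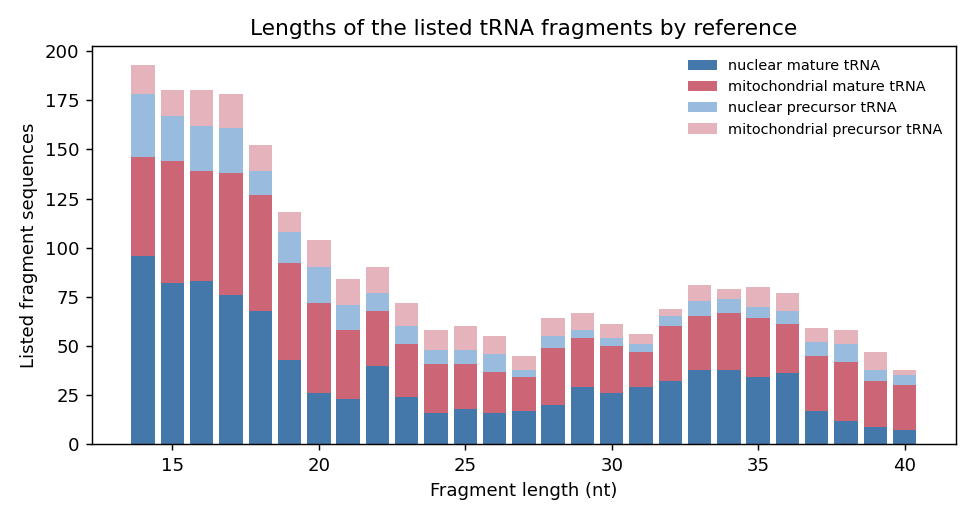
Number of listed fragment sequences (y axis) at each length in nt (x axis), stacked by the kind of reference they align to. Lengths of 14 to 18 nt hold 883 sequences and lengths of 28 to 36 nt hold 634.

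The second question is which kind of fragment was listed. The deposited annotation put 2084 fragments (86.7%) in the class Other and 321 (13.3%) in 9 named classes. The largest named class was tRF-5c, fragments of 28 to 32 nt from the 5′ end of the mature tRNA, with 85 members, 71 of them nuclear. It was followed by tRF-1, the trailer cut from the 3′ side of a precursor, with 69 members. The classes tRF-3a and tRF-3b, which run to the 3′ end of the mature tRNA, had 65 and 39 members, and all of these ended in CCA. The 5′ classes tRF-5a and tRF-5b had 19 and 13 members. The tiRNA-5 class, long 5′ pieces cut at or near the anticodon, had 21 members of 20 to 36 nt with a median of 34 nt. The tiRNA-3 class had 2 members, both mitochondrial, and tRF-2, from the inside of the tRNA, had 8 members, of which 6 were mitochondrial.

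Single members show what these classes hold; where lengths were tied, the first by identifier is given. Among the longest tRF-5c was the 32 nt sequence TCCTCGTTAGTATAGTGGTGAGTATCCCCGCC, bases 1 to 32 of the 75-base tRNA-Asp-GTC, which matched 2 reference sequences. Among the longest tiRNA-5 was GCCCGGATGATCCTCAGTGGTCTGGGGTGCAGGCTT, bases 1 to 36 of the 90-base selenocysteine tRNA, SeC-TCA. The longest tiRNA-3 was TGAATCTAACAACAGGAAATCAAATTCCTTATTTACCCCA, bases 32 to 71 of the mitochondrial tRNA-His. Among the longest tRF-1 was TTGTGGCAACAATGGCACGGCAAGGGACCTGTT, 33 nt from bases 113 to 145 of the 152-base precursor of the nuclear tRNA-His gene copy 1-7, where the trailer begins at base 113. Among the longest tRF-3b was CAACAAATCTCCACAATGACCA, bases 46 to 67 of the 67-base mitochondrial tRNA-Lys. Among the shortest tRF-5a was GGGGATGTAGCTCA, bases 1 to 14 of tRNA-Ala, which matched 7 references of 3 different Ala anticodons.

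The class Other held fragments from both ends of the mature tRNA as well as internal ones. Of the 236 mature fragments that began at base 1, 98 were in Other, with lengths of 17 to 40 nt. Of the 228 that ran exactly to the CCA end, 122 were in Other. A further 212 ended inside the CCA or just before it, all in Other: 133 lacked the last base of the reference, 49 lacked the last 2 and 30 lacked the whole CCA. Internal fragments, which reached neither end, were the most numerous placement, with 1178 of the 1854 mature fragments (63.5%). By compartment, 579 of the 955 nuclear mature fragments (60.6%) and 599 of the 899 mitochondrial mature fragments (66.6%) were internal. The 5′ end was the start of 185 nuclear mature fragments (19.4%) and of 51 mitochondrial ones (5.67%). With 1 entry per reference and 5′ start the nuclear share was 8.04%, or 37 of 460. These shares were not tested against each other, since overlapping sequences are not independent.

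The third question is which amino acid families were represented. Fragments of a single family covered 22 families, and 42 fragments matched tRNAs of more than 1 amino acid. By listed fragments, with nuclear and mitochondrial tRNAs joined, His had 274, Gly 262, Lys 249, Arg 224 and Val 209. The order depended on how fragments were counted: with each start on a reference counted once, Arg had 107, Gly 95, Lys 87, Val 78, Leu 78 and His 67. The make-up of these families differed. Gly fragments were mostly nuclear mature (202 of 262), as were Lys fragments (162 of 249) and Asp fragments (76 of 98). His fragments were mostly mitochondrial mature (190 of 274), and so were Ser (74 of 113), Cys (73 of 93), Met (55 of 82) and Trp (41 of 48). Arg fragments were spread over 59 nuclear mature, 77 mitochondrial mature, 45 nuclear precursor and 43 mitochondrial precursor sequences. Ala, iMet (the initiator tRNA) and SeC had no mitochondrial fragment. References are known here only through listed fragments, so these absences cannot tell a missing fragment from a missing reference. The smallest family was SeC, with 7 fragments.

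Among the 185 nuclear fragments from the 5′ end, Gly gave 59, Glu 30, Lys 28, Val 17, His 12 and Asp 10, while Arg, Leu, Met, Trp, Asn and Ile had none that began there. Of all 955 nuclear mature fragments, Gly gave 202, Lys 162, Asp 76, Glu 58, Val 48 and His 26. The families with none at base 1 gave 71 (Leu), 59 (Arg), 22 (Met), 6 (Trp), 6 (Asn) and 1 (Ile). For the smallest of these the absence says little, and no test of the families' shares was made. The lengths of the 185 had a median of 31 nt, and 135 of them (73.0%) were 28 to 36 nt long. This held for 42 of 59 Gly, 26 of 30 Glu and 25 of 28 Lys fragments. In 3 families no such fragment was 28 to 36 nt long: Ser had 7 of 14 to 18 nt, Ala 3 of 14 to 24 nt and Tyr 2, both of 16 nt. At the other end, fragments that reached the nuclear CCA end were most numerous for Ala (17 of 113), Leu (16) and Gln (10). Val had 9, Gly 8 and Thr 8, while Glu had 3, Arg 2, His 1 and Met 0.

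**Figure D2:**
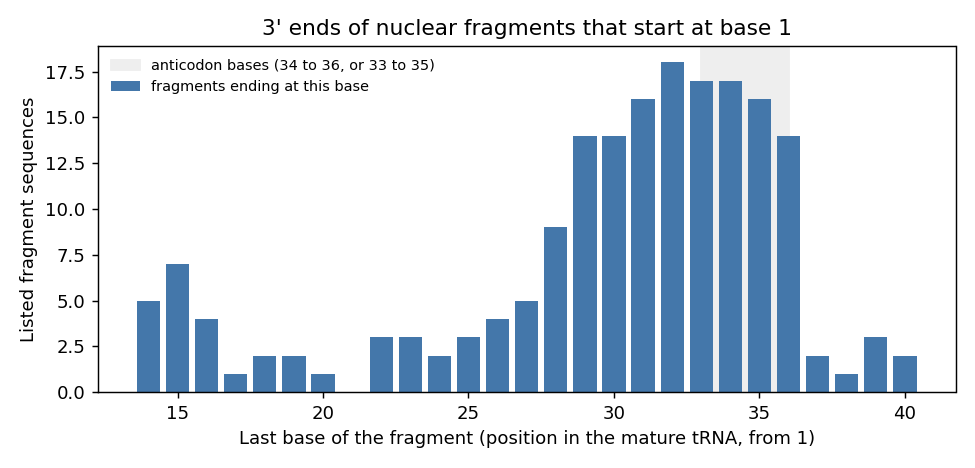
Number of listed nuclear fragments that start at base 1 of a mature tRNA (y axis) by the position of their last base (x axis), with bases 33 to 36 shaded, which hold the anticodon in all of these tRNAs but SeC. Bars are highest from base 29 to base 36, each with 14 to 18 fragments, and no later base has more than 3.

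Mitochondrial tRNAs were represented unevenly. Fragments came from 21 mature mitochondrial tRNAs. His led with 190 of the 899 (21.1%), followed by Val with 101, Arg with 77, Cys with 73 and Ser-GCT with 72, while Ile had 5 and Ser-TGA 2. The lead depended on how fragments were counted: the share of His was 10.6% with 1 entry per 5′ start, where His and Val both had 34, and 12.8% with 1 entry per 3′ end. Of the 190 His fragments, 180 were internal, 2 began at base 1 and 6 ran to the CCA end. Base 32 of the 71-base tRNA-His was covered by 181 of them. The Arg tRNA resembled it in placement, with 70 of 77 internal and base 32 covered by 69. Ser-GCT differed, with 21 of 72 fragments starting at base 1. Trp and Thr fragments lay at the 3′ side: 21 of 41 Trp and 11 of 18 Thr fragments ended at the CCA end. Such placement was not confined to them. All 37 Glu fragments covered base 57 of the 72-base tRNA, and 6 of 10 Leu-TAG fragments ended at the CCA end.

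**Figure D3:**
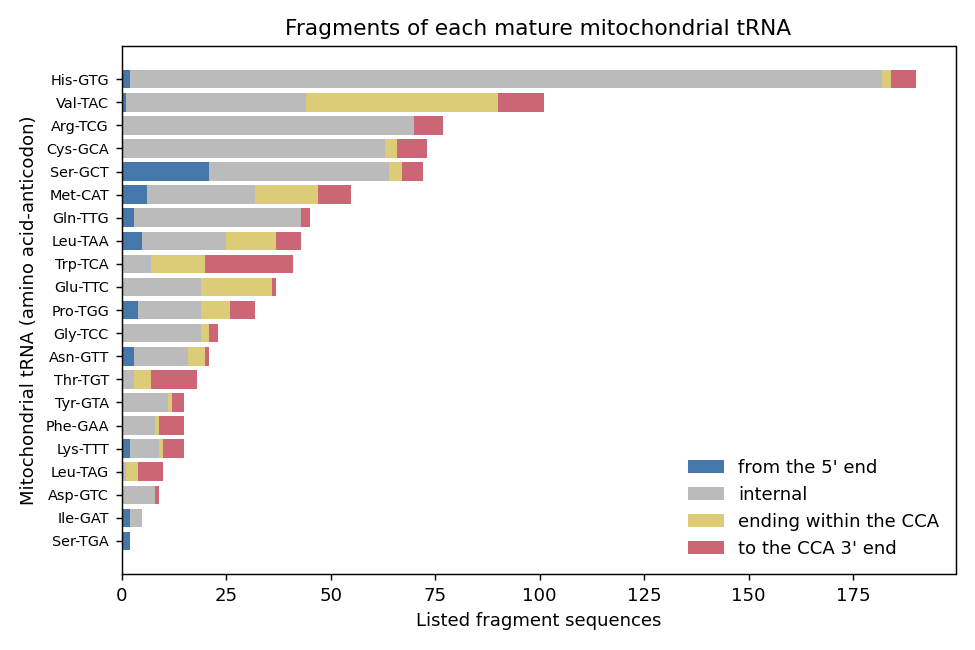
Number of listed fragment sequences (x axis) for each of the 21 mature mitochondrial tRNAs (y axis), with colours for their placement on the tRNA. His stands at 190, mostly internal, and Ser-GCT has the most fragments from the 5′ end, 21.

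Precursor fragments were the last group. Of the 283 nuclear precursor fragments, 97 began at the first base of the trailer and 82 further inside it. Another 63 ran from the leader into the body, 28 from the body into the trailer, 11 lay in the leader and 2 in the body. His-GTG gave the most (56 over 9 genes), then Arg-ACG (30 over 4 genes), iMet-CAT (18 over 3) and Thr-CGT (14 over 2). Of the 97 fragments from the first trailer base, 66 were classed tRF-1 and 31 Other. Of these 66 tRF-1 fragments, 64 ended in at least a pair of T, as did 19 of the 31 others. Among the shortest tRF-1, GAGGTGTGCCTTTT covered bases 114 to 127 of the 153-base precursor of an Arg-ACG gene.

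Mitochondrial precursor fragments had another make-up. Lys gave 60 of the 268, Arg 43 and Val 37. Another 35 were assigned to both the Asn and the Cys precursor, and Thr gave 20. The leader held 82 of the 268 (30.6%), of which Lys gave 32 and Arg 22, against 11 of 283 (3.89%) for nuclear precursors. Fragments that ran from the leader into the body went the other way, with 25 (9.33%) against 63 (22.3%). The 35 shared by Asn and Cys were placed on their first reference, and all counted as trailer. Their place on the second reference was not used. Mitochondrial tRNA genes lie close to other genes on shared transcripts, so their flanks of 40 bases need not be leader or trailer in the nuclear sense. A sequence listed in such a flank may come from a neighbouring gene and not from a tRNA. Among the longest listed sequences, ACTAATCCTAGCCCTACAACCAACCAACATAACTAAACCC covered all 40 bases after the tRNA-Val, bases 109 to 148 of its precursor.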

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

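The alternatives planned for the comparison of MCT with control, among them pseudocounts, filters, normalization, leaving out each replicate and the merging of identical sequences, were not run, because the per-sample values were not used. No paired analysis was possible because the value columns could not be matched to the numbered samples. The alternatives below were all chosen after seeing the data. Of 25 recomputed shares, 11 stayed inside the 95% Wilson interval of the reported share and 14 moved outside it. The share of fragments of mitochondrial origin, 48.5%, was 41.2% with 1 entry per reference and 5′ start, 38.4% with 1 entry per reference and 3′ end, 52.2% at 18 nt or more, and 63.6% among fragments with 1 reference. The share from nuclear precursors, 11.8%, was 14.6%, 20.4% and 13.6% with 1 entry per 5′ start, per 3′ end and with 1 reference. The share in the class Other, 86.7%, was 88.6% with 1 reference. The share of mitochondrial mature fragments from His, 21.1%, was 10.6% per 5′ start and 12.8% per 3′ end. The share of nuclear mature fragments that start at base 1, 19.4%, was 8.04% per 5′ start, 23.6% per 3′ end, 27.2% at 18 nt or more and 24.3% with 1 reference. By construction, counting each start or end once removes series of lengths that share it. The fall for mitochondrial His and for base 1 comes from such series. Keeping fragments of 1 reference removed 551 nuclear mature and 41 nuclear precursor fragments. It removed 37 mitochondrial precursor and no mitochondrial mature fragments, so the rise to 63.6% follows from that filter. The cause of the other shifts was not tested. Without mismatched fragments all 5 shares stayed inside their interval. No statement on depth can be made without the per-sample values.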

Other observations

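Of the 63 nuclear fragments that ran from a leader into the tRNA body, 26 began exactly 1 base before the body, and 18 of these 26 were from tRNA-His. They were 15 to 37 nt long, and all 18 began with C. The base before the body was C in all 9 nuclear His precursor references of the table. A further 12 nuclear His fragments began at base 1 of the mature tRNA. Mature tRNA-His is known for carrying an extra base at its 5′ end, usually a G added after transcription. A fragment that matches these references from the base before the body begins with C by construction. The 18 fragments therefore do not bear on an added G, and the presence of such a G was not tested.

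Among the tests below, those of T runs, of the anticodon and of size selection were chosen after the result was seen, and those of the cut between a pyrimidine and A and of the mitochondrial His starts before it. Each is on a list that had been selected in a way not given in the sources used here, so it bears on the listed sequences only.

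Nuclear trailer fragments ended at runs of T. After counting each start and length once, 79 of 94 fragments from the first trailer base (84.0%) ended in TT, against 22.0% for random lengths on the same trailers (permutation test, one-sided, p = 0.0001, the smallest that 10000 permutations can give, adjusted p = 0.000133). The test was first run on nuclear and mitochondrial precursors together and restricted to nuclear ones after that result was seen. Over both, 83 of 150 (55.3%) ended in TT against 16.1% for random lengths. Of these 83, 79 were nuclear, so the pooled share does not show the pattern for mitochondrial trailers, which were not tested alone. RNA polymerase III stops at runs of T. That trailer fragments end where the trailer's T run lies is what termination would leave, a candidate explanation given as a hypothesis.

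Many nuclear fragments from base 1 ended near the anticodon. Of the 185, 108 (58.4%) ended between 3 bases before and 3 bases after the anticodon, against 33.3% for random lengths on the same tRNAs (permutation test, one-sided, p = 0.0001, again the smallest possible, adjusted p = 0.000133). The anticodon began at base 33 or 34 in all of these tRNAs but SeC. With starts fixed at base 1, the test cannot separate ends near the anticodon from a preference for such lengths. Base 29, outside the window, held 14 ends, as did base 36, while base 37, inside it, held 2. The tables argue against size selection of the libraries as the whole cause of these lengths. Only 22.6% of the 579 internal nuclear fragments were 28 to 36 nt long, against 73.0% of the fragments from base 1. The baselines of these shares differ, since a shorter internal fragment has more possible places on a tRNA. Cleavage in the anticodon loop may account for the pattern and stays a hypothesis. A preference for cuts between a pyrimidine and A, the sites favoured by ribonucleases of the RNase A family, stayed open: 25 of the 185 (13.5%) were cut there against 10.3% for random lengths, which did not pass the threshold (permutation test, one-sided, p = 0.063, adjusted p = 0.063). Random lengths take every length as equally probable, and fragments that overlap are not independent, so these p-values describe the list and not the animals.

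A ladder of lengths at few starts was tested for the lead of mitochondrial tRNA-His. Its 190 fragments had 34 distinct 5′ starts, and mitochondrial tRNA-Val, with 101 fragments, also had 34, so the lead was gone when each start was counted once. Counted by distinct 3′ ends, His had 35, Ser-GCT 29 and Val 19, and its commonest start held 17 of the 190. The lead in 3′ ends does not count against a ladder, since a series of lengths at a shared start has many ends. By the rule fixed before the result, the tie in starts could not tell whether a ladder was the cause of the lead. The His starts were not few: 34 was the joint highest count among the 21 mitochondrial tRNAs, and none held more than 17 fragments. The lead over Val, with as many starts, lay in more listed lengths per start. No biological explanation was tested.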
